A study of Mus musculus with 52 samples.

How the data were processed

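Epithelium and adjacent stroma of mouse prostates were captured by laser, and the RNA was amplified and hybridized to Agilent whole mouse genome arrays of 41174 probes. There were 52 arrays on 13 slides of 4, read in 6 scans on 2 scanners. Samples carried the red dye and a universal mouse reference the green dye, with no dye swap. Per the labels CID was given at 2 mg per kg from 6 weeks of age, or from 12 weeks in JOCK mice of earlier experiments.

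The intensity values (processed and median signals) were made by the scanner software, Feature Extraction 10.7.3.1, per the file headers: processed signals are background-subtracted and dye-normalized within the array, and median signals are raw. The log10 values are the scanner software's ratios of red over green processed signals, per the file headers. The log2 values are the deposited series matrix of sample over reference; its exact method is not stated, and its columns correlate at 0.9176 to 0.9997 with normexp and loess values computed here, the lowest in ProCatxJOCK stroma without CID. Sequences and genome coordinates were not used. Probes were given gene symbols through their RefSeq accessions (24375 probes, 17016 genes).

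The design asked for mean signals, which the files lack, so its written fallback was used: log2 of red over green processed signals, loess-normalized within each array. Spots the software marked as not uniform or as population outliers were left out, so some genes have values on fewer arrays. A probe was kept if well above background on 75 percent of the arrays of at least 1 group, which left 11999 probes in epithelium and 12485 in stroma. The probe with the highest mean signal stood for its gene. Models were fitted per compartment with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 26 arrays, 6 groups, no covariate), and genes passed at an adjusted p (Benjamini-Hochberg) under 0.05 over all genes tested. Epithelium and stroma were compared over all 52 arrays, averaging the 6 groups. Standard errors of single genes are those of limma and pool the spread of all groups, so a group of 1 or 2 arrays is assumed to vary like the others. The 29 gene lists were written from general knowledge before the data were examined and tested with camera at a preset correlation of 0.01 and with an estimated one; a list with under 3 measured members was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

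Comparisons, tests and most alternatives were fixed before the data were examined. The rule for named genes was fixed then too: the 10 largest rises and 10 largest falls among passing genes, the 5 smallest p where fewer passed, up to 4 members of each list by smallest p, and 19 genes whatever their test. Of these 19, Axin2, Spry4, Tnc, Trp63 and Mki67 were measured in neither compartment and Ptprc not in epithelium, and 1 is not reported here. Of the 2080 gene results the rule gave, 137 are named in the text, picked after the alternatives had been run, by known function and, where possible, among calls that no left-out array ended. Tgfb1 in ProCatxJOCK and Fgfr1 in ProCatxJOCK stroma were above background on no array of that model and are given no direction.

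The alternatives fixed beforehand were Aquantile normalization, no background correction or the scanner log ratio or the series matrix, the sample channel alone (normexp, quantile between arrays), every probe tested, no filter and a stricter filter, array weights, trend and robust eBayes, only the groups compared, replicate and slide blocks, and each array left out in turn. Chosen after seeing the data were normexp correction (offset 50, the lowest 0.1 percent clipped), leaving out arrays with under 5000 detected spots, and the log10 number of detected spots as a covariate. On simulated data, of 100 genes with a log2 difference of 2 the fits recovered 45 in JOCK epithelium with CID, 63 in ProCatxJOCK epithelium with CID, 20 in the stromal difference of CID effects and 97 between the compartments. At a difference of 1 they recovered 5, 4, 1 and 87, so smaller changes could be missed. Correlations between arrays ran from 0.246 to 0.938, with 0 identical pairs. The deposited names give animals, used only as a block between the compartments, and ages and signs that were not used. Ages run from 24 to 50 weeks in ProCat, 24 to 34 in UbiCatxJOCK and 36 to 40 in JOCK. A plus or minus sign, which the labels do not explain, marks ProCat (3 plus and 5 minus per compartment) and UbiCatxJOCK (2 and 2 in epithelium, 1 and 3 in stroma). If it marks CID or an allele, these groups, all labelled CID, are mixed, and every comparison with them is in doubt.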

Results

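Gene expression was measured in the prostates of 4 mouse models, with epithelium and adjacent stroma captured by laser. In JOCK mice the drug AP20187, a chemical inducer of dimerization (CID), switches on an FGF receptor 1. ProCatxJOCK and UbiCatxJOCK mice are crosses that the design text describes as models of cancer sped up by Wnt signalling, and the labels do not say what the ProCat and UbiCat alleles express. Each of the 52 arrays held a sample (red) and a universal mouse reference (green). In each compartment 26 arrays formed 6 groups: 8 of ProCat with CID, 4 of UbiCatxJOCK with CID, 3 of ProCatxJOCK with CID, 3 of ProCatxJOCK without it, 6 of JOCK with CID and 2 of JOCK without it. The number of arrays limits the precision of every value.

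The sample signal differed between groups. Between 3211 and 28952 spots of an array were well above background in the sample channel (median 15698.5), against 25364 to 37577 in the reference channel. The ProCatxJOCK groups were the dimmest, with a median of 3486 spots in stroma without CID, 7583 in stroma with CID, 7487 in epithelium without CID and 5418 in epithelium with CID. The 5 arrays under 5000 spots were ProCatxJOCK without CID epithelium replicate 1, ProCatxJOCK without CID stroma replicates 1 and 2, ProCatxJOCK with CID stroma replicate 5 and ProCat epithelium replicate 3.

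**Figure D1:**
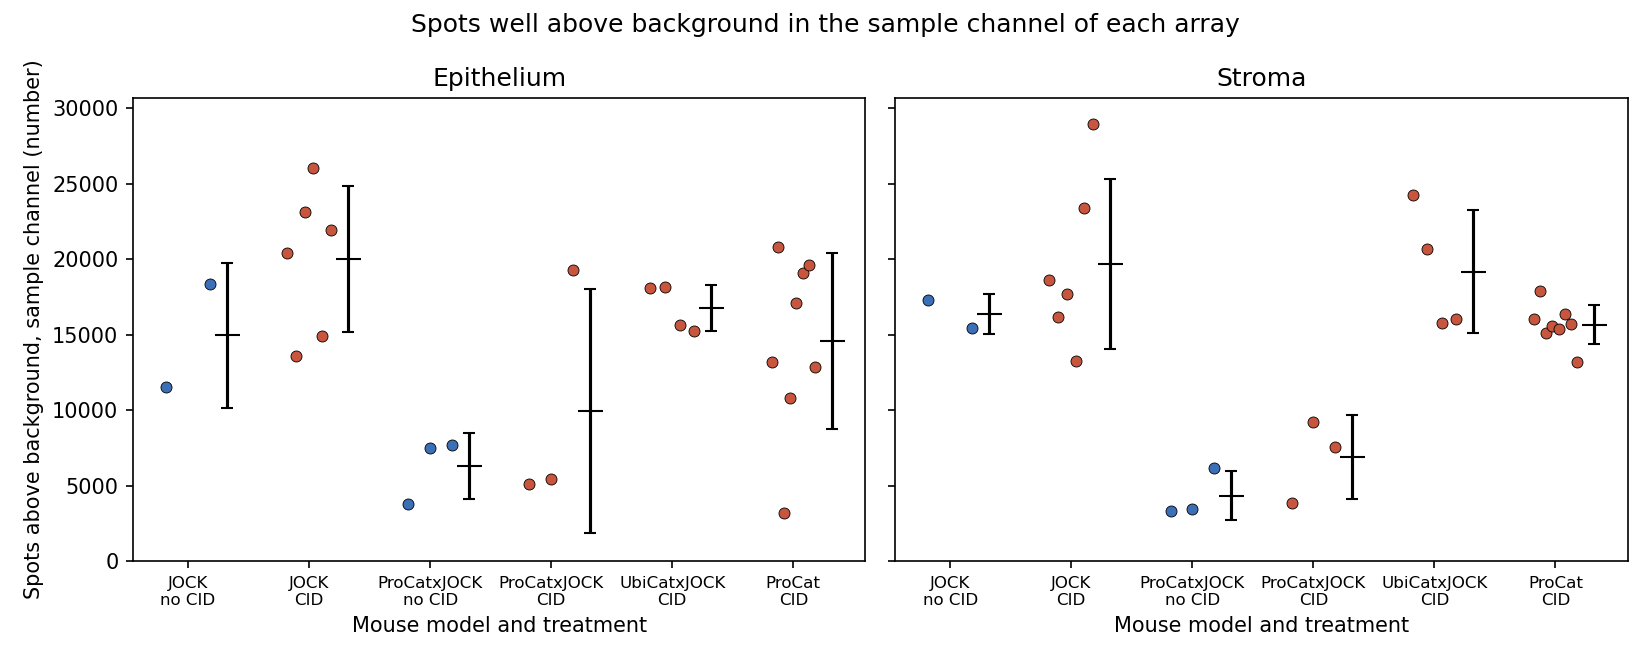
Number of spots well above background in the sample channel (vertical axis) for each array, by mouse model and treatment (horizontal axis). Each point is an array, the bars give the mean and SD, and the lowest medians are those of ProCatxJOCK, 5418 in epithelium with CID and 3486 in stroma without it.

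Differences are log2 differences of the sample over reference ratio, first group minus second, with their standard errors. Adjusted p-values are from limma over all genes tested, and p-values rest on the spread between samples as the labels give them. After an adjusted p, the arrays of the first group that lie on the stated side of the second group's mean are counted. A gene not well above background on any array of a group has only a bound there, written as at least N-fold. The bound was taken in the sample channel after loess and Aquantile normalization, so it is on another scale than the log ratio. It is open to dye bias, since no dyes were swapped. For lists, the median log2 difference of the members is followed by camera's adjusted p with a preset correlation and then by that with an estimated correlation.

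**Figure D2:**
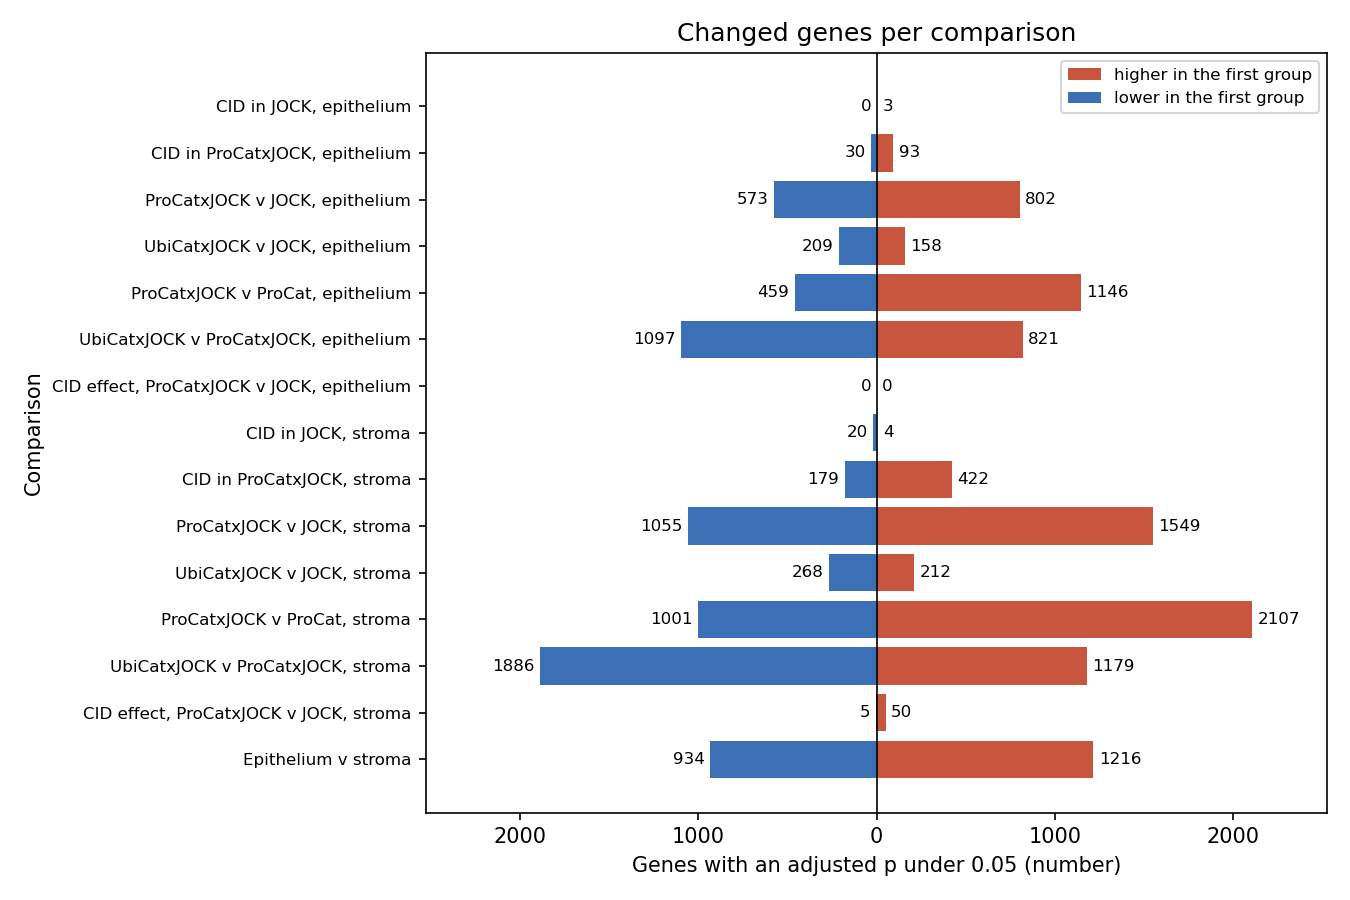
Number of genes with an adjusted p under 0.05 in each of the 15 comparisons, higher in the first group to the right of 0 and lower to the left. Bars run from 0 and 0 in the difference of the CID effect in epithelium to 2107 higher and 1001 lower in ProCatxJOCK against ProCat, stroma.

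Epithelium and stroma were compared over all models to show what was captured. Among the genes higher in epithelium were Azgp1, for a secreted glycoprotein, by 2.59 ± 0.44 (adjusted p = 1.99e-05, 24 of 26 arrays), and Lsr, of tricellular junctions, by 2.45 ± 0.30 (adjusted p = 2.34e-08, 25 of 26 arrays). The keratin gene Krt8 was higher by 0.93 ± 0.18 (adjusted p = 0.000118) and the adhesion molecule gene Epcam by 0.95 ± 0.21 (adjusted p = 0.000675), each in 24 of 26 arrays. Stroma held more of the matrix genes Col1a2 (-2.93 ± 0.22, adjusted p = 7.69e-14, 26 of 26 arrays) and Sparc (-2.39 ± 0.17, adjusted p = 3.63e-14, 25 of 25 arrays). The smooth muscle genes Myh11 (-2.94 ± 0.31, adjusted p = 8.92e-10) and Tpm2 (-2.48 ± 0.24, adjusted p = 1.56e-10) were also higher in stroma, in 26 of 26 and 24 of 24 epithelial arrays. So were the complement gene C1qc, expressed by macrophages (-4.48 ± 0.42, adjusted p = 4.74e-11), and Sfrp2, which encodes a secreted Wnt antagonist (-3.67 ± 0.32, adjusted p = 3.83e-12), each in 26 of 26 arrays.

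Further genes higher in stroma were Bmp1, a procollagen protease (-2.22 ± 0.20, adjusted p = 1.84e-11), Ccn2, a TGF-beta target (-1.95 ± 0.21, adjusted p = 2.31e-09), and the chemokine gene Ccl6 (-3.55 ± 0.42, adjusted p = 1.73e-08), in 26 of 26, 26 of 26 and 25 of 25 arrays. The endothelial cadherin gene Cdh5 was at least 1.32-fold higher in stroma (-3.19 ± 0.47, adjusted p = 1.54e-06, 25 of 26 arrays). Fgfr1 was lower in epithelium (-0.70 ± 0.16, adjusted p = 0.00163, 21 of 26 arrays) and Herpud1, of the endoplasmic reticulum stress response, was higher (1.61 ± 0.28, adjusted p = 2.97e-05, 24 of 26 arrays). Dusp6, an ERK phosphatase induced by FGF signalling, did not pass (0.41 ± 0.16, adjusted p = 0.0731, 14 of 25 arrays), but passed with the animal of the deposited names as a block (adjusted p = 0.0455) and without JOCK epithelium replicate 4 with CID or 1 without it, ProCatxJOCK epithelium replicate 2 with CID or UbiCatxJOCK stroma replicate 1 (0.0304 to 0.0405). Of the 13 fixed genes measured 6 did not pass, from -0.43 to 1.74. Across 10505 genes tested, 1216 were higher in epithelium and 934 higher in stroma. With the animal as a random block the count was 2634, and within the slide that held both compartments, 2 arrays against 2, it was 109.

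Of 29 lists, 3 were higher in epithelium and 8 in stroma, and 7 held with an estimated correlation. In stroma these were matrix genes (-1.19, adjusted p = 4.98e-32, 27 of 33 members lower over all genes and 29 adjusted over the list alone, adjusted p = 1.72e-05 with an estimated correlation), smooth muscle genes (-1.30, adjusted p = 2.45e-15, 13 of 18 and 14, adjusted p = 0.00807) and macrophage genes (-1.08, adjusted p = 9.94e-14, 12 of 17 and 13, adjusted p = 0.000611). TGF-beta genes (-0.55, adjusted p = 6.28e-06, 10 of 22 and 12, adjusted p = 0.0131), cytokines (-0.61, adjusted p = 8.45e-06, 11 of 18 and 12, adjusted p = 0.00338), endothelial genes (-0.55, adjusted p = 0.000553, 7 of 16 and 7, adjusted p = 0.0131) and epithelial-mesenchymal transition regulators (-0.41, adjusted p = 0.000553, 5 of 14 and 6, adjusted p = 0.0308) followed. Epithelial genes (0.94, adjusted p = 7.79e-06, 12 of 20 and 16) and endoplasmic reticulum genes (0.57, adjusted p = 1.51e-05, 11 of 20 and 14) did not hold with an estimated correlation (adjusted p = 0.0706 and 0.0983). Cell cycle genes (-0.24, adjusted p = 0.0114, 1 of 21 lower, adjusted p = 0.391) lost the call without ProCatxJOCK without CID epithelium replicate 3 (adjusted p = 0.0535). Mitochondrial genes (0.21, adjusted p = 0.0407, 6 of 28 higher, adjusted p = 0.532) lost it without any of 18 of the 52 arrays (adjusted p up to 0.0951). Within the shared slide, smooth muscle (-2.68, adjusted p = 6.16e-15), matrix (-0.53, adjusted p = 2.97e-05), macrophage (-0.79, adjusted p = 0.0216) and endothelial genes (-0.55, adjusted p = 0.0216) were lower in epithelium too, and endoplasmic reticulum and mitochondrial genes higher (each 0.58, adjusted p = 0.0216). There the TGF-beta, cytokine and transition lists were lower without passing (adjusted p from 0.281 to 0.487), epithelial genes were at 0.07 (adjusted p = 0.5), and cell cycle genes turned to 0.31 (adjusted p = 0.681). The signs of all 11 lists were the same under the other scalings.

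JOCK epithelium with and without CID, 6 arrays against 2, asked what switching on the receptor does. Dusp6, an FGF response gene, rose by 2.74 ± 0.48 (adjusted p = 0.0264, 6 of 6 treated arrays). Alb, for serum albumin, rose by 7.78 ± 1.09 (adjusted p = 0.00225, 6 of 6 arrays) and Noxa1, for an activator of NADPH oxidase, by 2.27 ± 0.40 (adjusted p = 0.0264, 6 of 6 arrays). Neither was above background on the 2 untreated arrays. In the sample channel Alb was at least 6.99-fold higher and Noxa1 at least 4.97-fold (4.82-fold by its log ratio). Fgfr1 itself did not pass (0.10 ± 0.52, adjusted p = 0.998, 4 of 6 arrays). Of the 12 fixed genes measured 11 did not pass, from -0.89 to 1.03.

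By limma 3 of 9647 genes were higher and 0 lower, against 679 at an unadjusted p under 0.05. The counts rested on single arrays: 9 genes passed without treated replicate 4, and 1 without treated replicate 5, 6, 7 or 8. Alb lost its call without untreated replicate 1 (adjusted p = 0.0656). Dusp6 lost it without any array but treated replicate 4 (adjusted p from 0.0518 to 0.521), and Noxa1 without treated replicate 5, 6, 7 or 8 or untreated replicate 2 (adjusted p from 0.0518 to 0.359). A fixed slide block gave 13 genes, and within each of the 2 slides 0 passed, where Dusp6 differed by 2.21 and 3.27 and Alb by 7.27 and 8.29. Each slide held 1 untreated array, and their effects correlated at 0.46 across genes. The split was 18 higher and 3 lower with no background correction and 16 higher and 4 lower with normexp correction. With only the groups compared 164 genes passed. None of 28 lists passed (smallest adjusted p = 0.302).

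In JOCK stroma the same question was asked, with 6 treated and 2 untreated arrays. The secreted carboxypeptidase gene Cpa6 fell by 4.92 ± 0.64 (adjusted p = 0.00034, 6 of 6 treated arrays) and was at least 24.3-fold lower, with no treated array above background. Rgs4, a regulator of G protein signalling, fell by 4.90 ± 0.90 (adjusted p = 0.0139, 6 of 6 arrays, at least 18.4-fold lower), and Fbxo32, a ubiquitin ligase gene of muscle wasting, fell by 2.90 ± 0.55 (adjusted p = 0.0186, 6 of 6 arrays). Tex101, a germ cell surface protein gene, fell by 4.12 ± 0.45 (adjusted p = 0.00123, 3 of 3 arrays, on 3 treated and 1 untreated arrays only). The 4 genes that rose were Tff3, a mucosal trefoil factor (3.98 ± 0.79, adjusted p = 0.0299, 6 of 6 arrays, at least 7.37-fold higher), and the integrin-like Itgbl1 (3.70 ± 0.77, adjusted p = 0.0382, 6 of 6 arrays against 1 untreated array). With them were the lectin receptor Cd302 (3.16 ± 0.53, adjusted p = 0.00632, 6 of 6 arrays) and Krtcap3, a keratinocyte-associated protein (2.46 ± 0.51, adjusted p = 0.0381, 6 of 6 arrays, at least 2.93-fold higher). Dusp6 did not pass (1.56 ± 0.38, adjusted p = 0.0846, 6 of 6 arrays), nor did Fgfr1 (0.07 ± 0.32, adjusted p = 0.996, 4 of 6 arrays) or any other of the 13 fixed genes measured, with values from -1.05 to 1.56.

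As a list, macrophage genes were higher with CID (0.98, adjusted p = 8.32e-07, 0 of 17 members passing over all genes and 0 adjusted over the list alone, adjusted p = 0.138 with an estimated correlation). Its member Ctss, a protease gene, was at 1.59 ± 0.56 (adjusted p = 0.383, 6 of 6 arrays). Cytokines were higher too (0.47, adjusted p = 0.00139, 0 of 17 members over all genes and 2 adjusted over the list alone, adjusted p = 0.138). Smooth muscle genes were lower (-1.10, adjusted p = 4.46e-05, 0 of 18 over all genes and 0 adjusted over the list alone, adjusted p = 0.58). The cytokine call was lost without untreated replicate 1 (adjusted p = 0.0873). All 3 lists kept their sign under the other scalings, with slide as a block (0.98, 0.47 and -1.13) and within the 2 slides (macrophage 0.73 and 0.94, cytokines 0.87 and 0.45, smooth muscle -1.24 and -0.58). The other 26 lists did not pass (smallest adjusted p = 0.081).

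In all, 4 of 9966 genes were higher and 20 lower. The count was 38 without treated replicate 1, 11 without 2, 12 without 3, 41 without 4, 14 without 5, 56 without untreated replicate 1 and 37 without untreated replicate 2. Untreated replicate 1 ended the call of Cd302 (adjusted p = 0.121) and untreated replicate 2 those of Rgs4 (-3.20, adjusted p = 0.396) and Fbxo32 (-1.35, adjusted p = 0.627), which was at -4.45 without untreated replicate 1. Itgbl1 lost its call without treated replicate 2, 3 or 5 (adjusted p up to 0.0696), Tff3 without those or either untreated array (up to 0.178), and Krtcap3 without treated replicate 2, 3, 5 or 6 or untreated replicate 1 (up to 0.6). A fixed slide block gave 41 genes, slide 2 alone gave 10 and slide 4 alone gave 36, each with 3 treated arrays against 1, and the effects of the 2 slides correlated at 0.31 across genes. The split was 2 higher and 4 lower with the sample channel alone and 7 and 19 with the scanner log ratio, and 13 genes passed with only the groups compared.

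ProCatxJOCK epithelium with and without CID, 3 arrays each, asked what the drug does in the cross. Among the genes that rose were Wfdc2, a secreted protease inhibitor family member, by 6.84 ± 0.77 (adjusted p = 2.32e-05, at least 102-fold) and Pglyrp1, a bacterial peptidoglycan receptor, by 7.49 ± 1.36 (adjusted p = 0.00771, at least 80.3-fold), each in 3 of 3 treated arrays. Ckmt1, for mitochondrial creatine kinase, rose by 4.10 ± 0.65 (adjusted p = 0.00228, 3 of 3 arrays, at least 16.5-fold) and Arfgef3, of a family of ARF exchange factors, by 3.73 ± 0.43 (adjusted p = 6.16e-05, 3 of 3 arrays, at least 10.4-fold). Dusp6 rose by 2.63 ± 0.48 (adjusted p = 0.0085, 3 of 3 arrays), and by 3.82 and 2.04 within slides 5 and 7. The Wnt ligand gene Wnt4 fell by 1.95 ± 0.32 (adjusted p = 0.00228, 3 of 3 arrays), with 1 of 3 arrays of each group above background. Fgfr1 did not pass (1.37 ± 0.52, adjusted p = 0.22, 3 of 3 arrays, at least 2.33-fold, 0.43 without treated replicate 1), and 11 of the 12 fixed genes measured did not, with values from -0.97 to 3.4.

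Cell cycle genes were lower with CID as a list (-0.58, adjusted p = 0.00125, 0 of 18 members passing over all genes and 0 adjusted over the list alone, adjusted p = 0.783 with an estimated correlation). Mitochondrial genes were lower (-0.47, adjusted p = 0.00938, 0 of 28 over all genes and 1 adjusted over the list alone, adjusted p = 0.783). Ribosomal protein genes were lower (-0.47, adjusted p = 0.00392, 0 of 30 on either count, adjusted p = 0.783), though their median was 0.02 with the sample channel alone. The cell cycle call was lost without untreated replicate 1 (-0.26, adjusted p = 0.295) and the mitochondrial call without that array or treated replicate 2 (-0.27, adjusted p up to 0.405). The ribosomal call was lost without treated replicate 1 or 2 (up to 0.059), and the median was -0.75 without 3. With slide as a block the medians were -0.59, -0.47 and -0.47 (adjusted p = 0.00134, 0.00863 and 0.00863). Within slides 5 and 7 they were -1.53 and -0.14 for the cell cycle, -0.23 and -0.49 for mitochondria and -0.07 and -0.83 for ribosomal proteins. The other 25 lists did not pass (smallest adjusted p = 0.0703).

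Of 9713 genes 93 were higher and 30 lower, and for 2 and 12 of these no array of the higher group was above background. The count was 190 without treated replicate 2, 186 without treated replicate 3, 62 without untreated replicate 2 and 230 without untreated replicate 3. With only the groups compared 1 gene passed. A fixed slide block gave 198, slide 5 alone 422 (1 array against 1) and slide 7 alone 230 (2 against 2). The effects of the 2 slides correlated at -0.09 across genes. The split was 17 higher and 0 lower with no background correction and with normexp correction, 18 and 0 with the series matrix, and 205 and 139 with the sample channel alone.

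**Figure D3:**
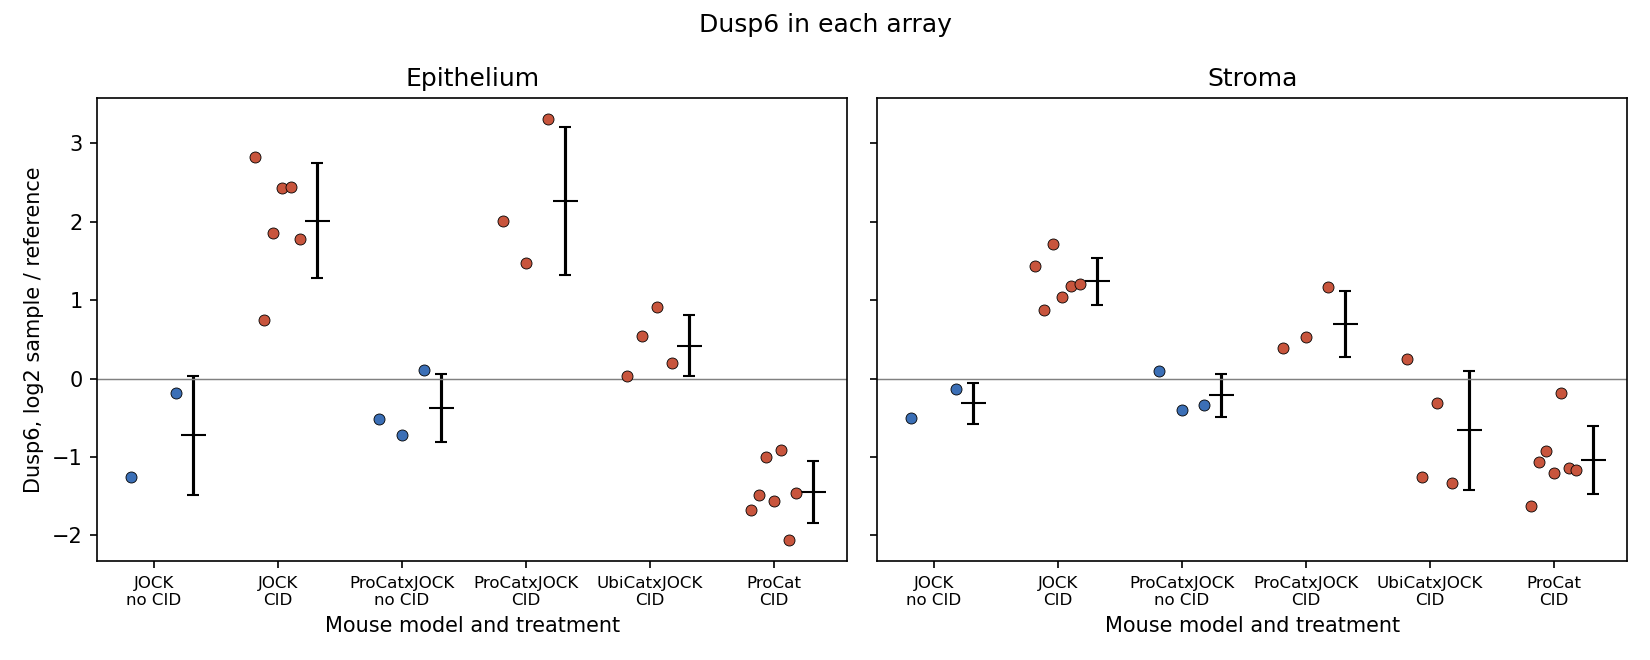
Log2 of sample over reference for Dusp6 (vertical axis) in each array, by model and treatment (horizontal axis), with means and SD. In epithelium JOCK arrays with CID span 0.75 to 2.83 against -1.26 and -0.19 without it, and UbiCatxJOCK arrays span 0.03 to 0.91.

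ProCatxJOCK stroma was compared in the same way, 3 arrays with CID against 3 without it. Those that rose included C1qc by 5.09 ± 0.88 (adjusted p = 0.00165, at least 5.97-fold) and Serping1, the C1 inhibitor, by 4.91 ± 0.92 (adjusted p = 0.00295, at least 9.21-fold), each in 3 of 3 treated arrays. The enkephalin precursor gene Penk rose by 5.76 ± 1.27 (adjusted p = 0.0104, 3 of 3 arrays, 3.12 without untreated replicate 1) and Cygb, for cytoglobin, by 4.22 ± 0.67 (adjusted p = 0.0011, 3 of 3 arrays, at least 9.08-fold). The membrane protein gene Tmem109 fell by 2.31 ± 0.37 (adjusted p = 0.00113, 2 of 2 arrays), the cytochrome oxidase gene Cox6c by 0.89 ± 0.20 (adjusted p = 0.0121, 3 of 3 arrays) and the glucose transporter gene Slc2a1 by 1.22 ± 0.34 (adjusted p = 0.0375, 3 of 3 arrays). Slc2a1 lost its call without treated replicate 6 or 7 or untreated replicate 1 (adjusted p up to 0.189). Dusp6 did not pass (0.91 ± 0.38, adjusted p = 0.159, 3 of 3 arrays), nor did any other of the 13 fixed genes measured, with values from -0.97 to 3.78.

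Mitochondrial genes were lower as a list (-0.80, adjusted p = 1.2e-09, 4 of 28 over all genes and 11 adjusted over the list alone, adjusted p = 0.505 with an estimated correlation), as were hypoxia and glycolysis genes (-0.66, adjusted p = 0.00179, 1 of 18 and 4, with 1 higher, adjusted p = 0.505) and cell cycle genes (-0.42, adjusted p = 0.000607, 1 of 21 and 3, adjusted p = 0.505). Smooth muscle genes were lower (-1.01, adjusted p = 0.00428, 0 of 18 on either count, adjusted p = 0.636). Macrophage genes were higher (0.61, adjusted p = 0.0132, 6 of 17 on either count, adjusted p = 0.505). The signs held under the other scalings. Without untreated replicate 1 the cell cycle call was lost (-0.25, adjusted p = 0.0532), hypoxia genes were at -0.43 and smooth muscle genes at -1.72. The macrophage call was lost without treated replicate 5 (0.40) or 7 (0.30) or untreated replicate 3 (adjusted p up to 0.144) and the smooth muscle call without treated replicate 5 or untreated replicate 2 or 3 (-0.41 without the last, adjusted p up to 0.308). With slide as a block the 5 medians were unchanged. For mitochondria, hypoxia, the cell cycle, smooth muscle and macrophages they were -1.11, -0.58, -0.50, -1.33 and -0.43 within slide 5 and -0.65, -0.52, -0.58, -0.85 and 0.97 within slide 6, so the macrophage median changed sign. The other 24 lists did not pass (smallest adjusted p = 0.146).

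Of 10133 genes 422 were higher and 179 lower, with no array of the higher group above background for 93 and 37 of them. The count was 327 without treated replicate 7 and 206 without untreated replicate 1. With only the groups compared it was 0, so no call held. A fixed slide block gave 693, slide 5 alone 119 (1 array against 1) and slide 6 alone 673 (2 against 2), and their effects correlated at 0.19 across genes. The split was 119 higher and 8 lower with no background correction, 102 and 5 with normexp, 53 and 3 with the series matrix and 464 and 454 with the sample channel alone.

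The CID effects of ProCatxJOCK and JOCK were compared, to test whether the drug acts differently in the cross. In epithelium no gene passed by limma (0 higher and 0 lower of 9628, 679 at an unadjusted p under 0.05). The smallest p belonged to Arfgef3 (3.12 ± 0.62), the pre-microRNA exporter gene Xpo5 (2.75 ± 0.52) and the homeobox gene Pitx3 (3.38 ± 0.67), none of them above background on an untreated ProCatxJOCK array. With them were the peroxiredoxin gene Prdx6b (-2.60 ± 0.53) and Espn, of actin bundling (-2.45 ± 0.47), and all 5 had an adjusted p of 0.112, in 3 of 3 treated ProCatxJOCK arrays. A further Espn probe gave 0.62, and the probes of Prdx6b pointed both ways in the CID effect of ProCatxJOCK alone (-3.82 and 1.80). Dusp6 rose with CID in both models and the difference of its effects did not pass (-0.11 ± 0.68, adjusted p = 0.985, 0 of 3 arrays). Mitochondrial genes were lower in ProCatxJOCK relative to JOCK (-0.60, adjusted p = 0.00111, 0 of 28 on either count, adjusted p = 0.746 with an estimated correlation). Cell cycle genes were lower (-0.63, adjusted p = 0.0215, 0 of 18 on either count, adjusted p = 0.746) but at 0.04 with the series matrix.

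A fixed slide block let 4 genes pass, and put the 2 lists at -0.64 (adjusted p = 0.00123) and -0.63 (adjusted p = 0.0175). The mitochondrial call was lost without treated ProCatxJOCK replicate 2 (adjusted p = 0.0702). The cell cycle call was lost without untreated JOCK replicate 2, treated ProCatxJOCK replicate 1 or 3 or untreated ProCatxJOCK replicate 1 or 2 (up to 0.571). Its median was -0.37 and -0.95 without treated ProCatxJOCK replicates 1 and 2 and -0.22 without untreated ProCatxJOCK replicate 1. Leaving out an array let 1 gene pass (untreated JOCK replicate 1 or 2, or treated ProCatxJOCK replicate 2, where it was Xpo5), 5 (untreated ProCatxJOCK replicate 3, Arfgef3 and Xpo5 among them) or 6 (treated ProCatxJOCK replicate 3, with Pitx3, Espn and Prdx6b), these at adjusted p from 0.0106 to 0.0424. The other 26 lists did not pass (smallest adjusted p = 0.0642), nor did any of the 12 fixed genes measured, with values from -1.63 to 2.41.

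In stroma 50 of 9957 genes had a higher CID effect in ProCatxJOCK than in JOCK and 5 a lower one. Tex101 was higher by 4.97 ± 0.60 (adjusted p = 0.00232, 2 of 2 arrays). So were the interferon-induced GTPase gene Gbp2b, by 4.97 ± 1.01 (adjusted p = 0.0246, 3 of 3 arrays) and the inositol phosphate kinase gene Itpkc, by 4.42 ± 0.81 (adjusted p = 0.0105, 3 of 3 arrays). Cd302 was lower by -3.59 ± 0.74 (adjusted p = 0.0262, 2 of 3 arrays) and G6pdx, of the pentose phosphate pathway, by -2.34 ± 0.47 (adjusted p = 0.0246, 3 of 3 arrays). Itpkc and Gbp2b were above background on no untreated ProCatxJOCK array and G6pdx on no treated one. Dusp6 did not pass (-0.65 ± 0.53, adjusted p = 0.635, 0 of 3 arrays), and the 13 fixed genes measured ran from -1.90 to 3.37 without passing. Untreated JOCK replicate 2 ended the call of Itpkc (adjusted p = 0.121). Either untreated JOCK array or untreated ProCatxJOCK replicate 2 ended those of Gbp2b (up to 0.0894) and Cd302 (up to 0.122). Either untreated JOCK array, treated ProCatxJOCK replicate 7 or untreated ProCatxJOCK replicate 1 ended that of G6pdx (up to 0.0894). Mitochondrial genes were lower (-0.85, adjusted p = 4.23e-07, 0 of 28 on either count, adjusted p = 0.971 with an estimated correlation, -0.87 with slide as a block) and under the other scalings too. The other 28 lists did not pass (smallest adjusted p = 0.181).

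The stromal count was 76 with slide as a block and 10 with only the groups compared. It was 24 without treated JOCK replicate 2, 29 without treated JOCK replicate 6, 6 without untreated JOCK replicate 2, 163 without treated ProCatxJOCK replicate 5, 30 without treated ProCatxJOCK replicate 7, 25 without untreated ProCatxJOCK replicate 1 and 98 without untreated ProCatxJOCK replicate 3. With the sample channel alone the split was 19 higher and 17 lower.

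The remaining comparisons set models against each other, all with CID, to ask what the added alleles change. No slide held more than 1 model, so a model and its slides could not be told apart, and ages differ too: the design text gives 40 weeks for JOCK and 24 weeks for the crosses. ProCatxJOCK against JOCK epithelium, 3 arrays against 6, asked what the ProCat allele adds. Alb fell by 6.49 ± 0.95 (adjusted p = 0.000211, at least 5.19-fold lower) and the ankyrin repeat gene Ankrd22 by 4.16 ± 0.80 (adjusted p = 0.00209, at least 2.07-fold lower), each in 3 of 3 arrays. The transcription factor gene Arid5b rose by 3.07 ± 0.51 (adjusted p = 0.000682, 3 of 3 arrays), and the respiratory chain gene Uqcrc1 by 1.29 ± 0.29 (adjusted p = 0.00583, 3 of 3 arrays). Fgfr1 was higher (2.89 ± 0.45, adjusted p = 0.000366, 3 of 3 arrays) but at -0.15 with the sample channel alone, and Dusp6 did not pass (0.25 ± 0.42, adjusted p = 0.728, 1 of 3 arrays). The beta-catenin gene Ctnnb1 was lower (-1.59 ± 0.37, adjusted p = 0.00765, 3 of 3 arrays), a call lost without ProCatxJOCK replicate 1 or 2 (up to 0.0599). Of the 12 fixed genes measured 9 did not pass, from -1.96 to 0.31.

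As a list, ribosomal protein genes were lower (-0.90, adjusted p = 1.58e-06, 7 of 30 over all genes and 12 adjusted over the list alone, adjusted p = 0.893 with an estimated correlation), Rpl14 by -1.90 ± 0.30 (adjusted p = 0.000425, 3 of 3 arrays), though with the sample channel alone the list's test pointed up at a median of -0.56. Mitochondrial genes were lower (-0.74, adjusted p = 0.0273, 4 of 28 lower and 1 higher over all genes, 7 and 2 adjusted over the list alone, adjusted p = 0.893) but higher with the sample channel alone (0.25). That call was lost without JOCK replicate 3, 6 or 8 or ProCatxJOCK replicate 2 (-0.36 without the last, adjusted p up to 0.36). The other 26 lists did not pass (smallest adjusted p = 0.132). Of 9744 genes 802 were higher and 573 lower, and 95 of those higher were above background on no ProCatxJOCK array. The count was 667 without ProCatxJOCK replicate 1, 613 without 2 and 2121 without 3, and 1184 with slide as a random block. The split was 400 higher and 1009 lower with the sample channel alone, where the median of all genes moved by -0.17, and 163 and 1076 with the scanner log ratio, where it moved by -0.51.

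In stroma the same comparison gave 1549 higher and 1055 lower of 10141 genes. The neuropeptide gene Grp fell by 5.35 ± 1.08 (adjusted p = 0.00127, 3 of 3 arrays, at least 1.79-fold lower) and Tshb, for a thyrotropin subunit, by 6.28 ± 1.28 (adjusted p = 0.00136, 3 of 3 arrays, at least 4.14-fold lower). Syt13, a synaptotagmin gene, rose by 3.95 ± 0.48 (adjusted p = 2.36e-05, 3 of 3 arrays, 1 of 3 above background) and Gbp2b by 3.11 ± 0.62 (adjusted p = 0.00111, 3 of 3 arrays). Ctnnb1 was lower (-1.73 ± 0.41, adjusted p = 0.00412, 3 of 3 arrays) but at 0.13 with the number of detected spots as a covariate, and Dusp6 did not pass (-0.55 ± 0.33, adjusted p = 0.226, 3 of 3 arrays). Of the 13 fixed genes measured 9 did not pass, from -2.79 to 0.90. Mitochondrial genes were lower (-0.75, adjusted p = 0.000239, 13 of 28 lower and 1 higher on either count, adjusted p = 0.915 with an estimated correlation), the ATP synthase gene Atp5a1 by -1.67 ± 0.29 (adjusted p = 0.00038, 3 of 3 arrays) and Cox4i1 by -1.50 ± 0.30 (adjusted p = 0.00117, 3 of 3 arrays). Ribosomal protein genes were lower (-0.60, adjusted p = 0.00124, 10 of 30 on either count, adjusted p = 0.915, -0.34 without ProCatxJOCK replicate 5), Rpl14 by -1.51 ± 0.28 (adjusted p = 0.000615, 3 of 3 arrays). So were endoplasmic reticulum genes (-0.68, adjusted p = 0.00294, 5 of 22 on either count, adjusted p = 0.915), Herpud1 by -1.57 ± 0.30 (adjusted p = 0.000894, 3 of 3 arrays).

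The signs of these 3 lists held under the other scalings, and the other 26 lists did not pass (smallest adjusted p = 0.156). No ProCatxJOCK array was above background for 519 of the 1549 genes called higher. Under a random slide block 2220 genes passed. The split was 317 higher and 1007 lower with the sample channel alone and 550 and 2057 with the scanner log ratio. The median of all genes moved by -0.18 and -0.54 under these, by -0.14 with the series matrix and by -0.11 with normexp.

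UbiCatxJOCK against JOCK epithelium, 4 arrays against 6, asked what the UbiCat allele adds. The RNA-binding protein gene Elavl2 rose by 3.20 ± 0.56 (adjusted p = 0.00292, 4 of 4 arrays, at least 4.06-fold) and Svs5, a seminal vesicle secretory gene, by 5.40 ± 1.14 (adjusted p = 0.0113, 4 of 4 arrays), a call lost without UbiCatxJOCK replicate 2 (adjusted p = 0.0519). Sval1, also of the seminal vesicle list, fell by 2.04 ± 0.49 (adjusted p = 0.0222, 4 of 4 arrays), a call lost without JOCK replicate 5 or UbiCatxJOCK replicate 1, 2 or 3 (up to 0.0976). Alb fell by 6.17 ± 0.86 (adjusted p = 0.000589, 4 of 4 arrays), the mucosal chemokine gene Cxcl17 by 4.68 ± 0.98 (adjusted p = 0.0113, 4 of 4 arrays, at least 4.79-fold lower) and the splicing factor gene Tra2b by 4.75 ± 0.74 (adjusted p = 0.00128, 4 of 4 arrays). Dusp6 was lower by -1.59 ± 0.38 (adjusted p = 0.02, 4 of 4 arrays), a call lost without UbiCatxJOCK replicate 1, 2 or 4 (up to 0.0879), while Fgfr1 did not pass (0.69 ± 0.41, adjusted p = 0.365, 4 of 4 arrays). Smooth muscle genes were higher (1.01, adjusted p = 3.97e-05, 3 of 15 over all genes and 7 adjusted over the list alone, adjusted p = 0.127 with an estimated correlation), Tpm2 by 2.51 ± 0.43 (adjusted p = 0.003, 4 of 4 arrays). So were matrix genes (0.59, adjusted p = 0.000128, 4 of 25 and 11, with 1 lower, adjusted p = 0.127, but -0.03 with the sample channel alone), the matrix proteoglycan gene Dcn by 2.25 ± 0.41 (adjusted p = 0.00591, 4 of 4 arrays). Ribosomal protein genes (0.73, adjusted p = 3.97e-05, 1 of 30 on either count, adjusted p = 0.503) and cell cycle genes (0.33, adjusted p = 0.0157, 0 of 18 on either count, adjusted p = 0.503) were higher, but at -0.14 and -0.12 with the sample channel alone.

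Of 9725 genes 158 were higher and 209 lower. The cell cycle call was lost without UbiCatxJOCK replicate 4 (adjusted p = 0.0701). The other 24 lists did not pass (smallest adjusted p = 0.0601), nor did 11 of the 12 fixed genes measured, from -1.25 to 1.67. The count was 223, 237 and 244 without JOCK replicates 5, 7 and 8, and 88, 139 and 130 without UbiCatxJOCK replicates 1, 2 and 3. It was 248 with slide as a random block and 1460 with only the groups compared, and the split was 584 higher and 438 lower with the sample channel alone.

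In UbiCatxJOCK stroma Plppr1, a brain-enriched membrane protein gene, rose by 5.23 ± 0.77 (adjusted p = 0.000257, 4 of 4 arrays, at least 3.36-fold) and Spry2, an inhibitor of receptor tyrosine kinase signalling, by 4.33 ± 0.84 (adjusted p = 0.00432, 4 of 4 arrays). The chemokine gene Ccl8 fell by 4.68 ± 0.77 (adjusted p = 0.000764), the collagen-binding proteoglycan gene Lum by 3.91 ± 0.84 (adjusted p = 0.00914), Tff3 by 3.56 ± 0.63 (adjusted p = 0.00151), Tra2b by 4.66 ± 0.36 (adjusted p = 4.07e-08) and Dusp6 by 1.90 ± 0.30 (adjusted p = 0.000566), each in 4 of 4 arrays. Fgfr1 did not pass (-0.08 ± 0.25, adjusted p = 0.877, 2 of 4 arrays). Smooth muscle genes were higher (0.96, adjusted p = 0.000995, 1 of 18 over all genes and 3 adjusted over the list alone, adjusted p = 0.616 with an estimated correlation), Csrp1, for a LIM protein of smooth muscle, by 2.60 ± 0.51 (adjusted p = 0.00497, 4 of 4 arrays). Macrophage genes were lower (-1.05, adjusted p = 0.0308, 1 of 17 and 4, adjusted p = 0.616). Seminal vesicle genes were higher (4.06, adjusted p = 0.0308, 2 of 5 over all genes, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.616), Svs4 by 4.99 ± 1.29 (adjusted p = 0.0283, 4 of 4 arrays, at least 6.56-fold), a call lost without UbiCatxJOCK replicate 2 or 4 (up to 0.105). Also higher were ribosomal protein genes (0.45, adjusted p = 0.00524, 1 of 30 on either count, adjusted p = 0.682) but at -0.66 with the sample channel alone.

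Of 10136 genes 212 were higher and 268 lower in that comparison of 4 arrays with 6. The macrophage call was lost without JOCK replicate 2 or 5 or UbiCatxJOCK replicate 3 or 4 (up to 0.104). Without UbiCatxJOCK replicate 3 the ribosomal call was lost (median 0.21, adjusted p = 0.27), and the seminal vesicle call without JOCK replicate 2 or 6 or UbiCatxJOCK replicate 2 or 4 (up to 0.172). The other 25 lists did not pass (smallest adjusted p = 0.23), nor did 12 of the 13 fixed genes measured, from -1.34 to 2.34. The count was 281 without JOCK replicate 4 and 264, 245, 271 and 227 without UbiCatxJOCK replicates 1, 2, 3 and 4. A random slide block gave 164.

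ProCatxJOCK against ProCat epithelium, 3 arrays against 8, asked what the FGF receptor adds to the ProCat allele. Dusp6 was higher by 3.71 ± 0.41 (adjusted p = 8e-06, 3 of 3 arrays). Also higher were Pglyrp1 by 6.05 ± 1.13 (adjusted p = 0.00109), Wfdc2 by 5.58 ± 0.64 (adjusted p = 9.02e-06), Tff3 by 5.00 ± 0.81 (adjusted p = 0.000335, at least 7.17-fold) and Clu, for the chaperone clusterin, by 4.54 ± 0.83 (adjusted p = 0.000963), each in 3 of 3 arrays. Ckmt1 rose by 5.59 ± 0.56 (adjusted p = 6.66e-06, 3 of 3 arrays), and Fgfr1 was higher by 2.09 ± 0.43 (adjusted p = 0.00263, 3 of 3 arrays) but at -0.22 with the sample channel alone and 1.15 without ProCatxJOCK replicate 1. Dcn fell by 2.11 ± 0.41 (adjusted p = 0.00211, 3 of 3 arrays), Sel1l, of endoplasmic reticulum degradation, by 1.81 ± 0.34 (adjusted p = 0.00104, 3 of 3 arrays) and Rpl14 by 1.68 ± 0.29 (adjusted p = 0.00061, 3 of 3 arrays). The Wnt ligand gene Wnt7a was higher by 1.45 ± 0.34 (adjusted p = 0.00712, 3 of 3 arrays), a call lost without ProCatxJOCK replicate 2 (0.73, adjusted p = 0.0856). Of the 12 fixed genes measured 8 did not pass, from -3.40 to 1.90.

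Of 28 lists 7 passed here and none held with an estimated correlation (adjusted p from 0.55 to 0.722). Lower were ribosomal protein genes (-0.54, adjusted p = 0.000281, 1 of 30 on either count, 0.69 with the sample channel alone), endoplasmic reticulum genes (-0.57, adjusted p = 0.00959, 4 of 22 lower and 1 higher on either count, 0.40 with it) and cell cycle genes (-0.25, adjusted p = 0.0319, 3 of 18 on either count, 0.18 with it). Smooth muscle genes were lower (-0.64, adjusted p = 0.0256, 5 of 15 over all genes, 5 lower and 1 higher adjusted over the list alone). So were matrix genes (-0.31, adjusted p = 0.0342, 4 of 25 lower and 2 higher over all genes, 6 and 2 adjusted over the list alone), whose median was 0.18 with the series matrix and 0.01 with normexp. Wnt ligands and receptors were higher (0.68, adjusted p = 0.0342, 7 of 20 over all genes, 9 higher and 1 lower adjusted over the list alone) but at -0.11 with the sample channel alone. Epithelial genes were higher (0.83, adjusted p = 0.0467, 6 of 20 on either count). Without ProCatxJOCK replicate 3 the smooth muscle (adjusted p = 0.16), Wnt, cell cycle, matrix and epithelial calls were lost, and the last 4 also without ProCat replicate 3. The cell cycle and epithelial calls were lost without ProCatxJOCK replicate 1, the matrix call without ProCat replicate 6 and the epithelial call without ProCat replicate 8, with adjusted p up to 0.394. Without ProCatxJOCK replicate 3 the cell cycle, matrix and ribosomal medians were -0.09, -0.51 and -0.85. Without ProCatxJOCK replicate 2 the first 2 were -0.64 and -0.53, without ProCat replicate 1 or 4 that of matrix genes was -0.47, and without ProCat replicate 3 the ribosomal one was -0.91. The other 21 lists did not pass (smallest adjusted p = 0.0622).

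Of 9745 genes 1146 were higher and 459 lower, and 54 of those higher were above background on no ProCatxJOCK array. The count was 945 without ProCatxJOCK replicate 2, 486 with only the groups compared and 1380 with slide as a random block. The split was 713 higher and 136 lower with no background correction, 619 and 136 with normexp, 1049 and 1375 with the sample channel alone and 272 and 561 with the scanner log ratio. The median of all genes moved by -0.21 and -0.37 under the last pair.

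In stroma 2107 of 10136 genes were higher and 1001 lower in ProCatxJOCK than in ProCat. Cygb rose by 3.95 ± 0.57 (adjusted p = 6.03e-05), Wfdc2 by 3.41 ± 0.66 (adjusted p = 0.000637), Syt13 by 4.20 ± 0.46 (adjusted p = 7.63e-06) and Dusp6 by 1.74 ± 0.32 (adjusted p = 0.000478), each in 3 of 3 arrays. Camk2n1, for an inhibitor of a calcium-dependent kinase, fell by 5.40 ± 0.98 (adjusted p = 0.000402, 3 of 3 arrays, at least 2.48-fold lower). The smooth muscle list was lower (-0.61, adjusted p = 0.0207, 5 of 18 lower and 1 higher over all genes, 6 and 1 adjusted over the list alone, adjusted p = 0.803 with an estimated correlation), Csrp1 by -1.82 ± 0.54 (adjusted p = 0.0137, 3 of 3 arrays), a call lost without ProCatxJOCK replicate 5 (adjusted p = 0.102). The ribosomal list was lower (-0.79, adjusted p = 1.09e-05, 10 of 30 on either count, adjusted p = 0.722), Rpl14 by -1.69 ± 0.27 (adjusted p = 0.000108, 3 of 3 arrays), though with the sample channel alone the list's test pointed up at a median of -0.31. Mitochondrial genes (-0.73, adjusted p = 3.95e-05, 9 of 28 over all genes and 10 adjusted over the list alone, adjusted p = 0.722), Cox4i1 by -1.68 ± 0.28 (adjusted p = 0.000168, 3 of 3 arrays), and endoplasmic reticulum genes (-0.48, adjusted p = 0.00366, 6 of 22 and 7, with 1 higher, adjusted p = 0.722), Herpud1 by -2.13 ± 0.29 (adjusted p = 3.45e-05, 3 of 3 arrays), were lower but at 0.11 and 0.10 with the sample channel alone.

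The smooth muscle list lost its call without ProCatxJOCK replicate 5 or 7 (adjusted p up to 0.0967) and was at -1.09 without 6, and the other 25 lists did not pass (smallest adjusted p = 0.0628). Of the 13 fixed genes measured 8 did not pass, from -1.54 to 1.30. No ProCatxJOCK array was above background for 619 of the 2107 genes called higher. Under a random slide block 2702 genes passed. The split was 1434 higher and 401 lower with no background correction, 432 and 1339 with the sample channel alone and 656 and 1944 with the scanner log ratio. The median of all genes moved by -0.27 and -0.56 under the last pair, by -0.18 with the series matrix, by -0.16 with normexp and by -0.15 with no background correction.

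UbiCatxJOCK was set against ProCatxJOCK, 4 epithelial arrays against 3, to ask how the crosses differ. Wfdc2 fell by 4.78 ± 0.72 (adjusted p = 0.000391), Ckmt1 by 4.60 ± 0.61 (adjusted p = 0.000198), Tff3 by 4.31 ± 0.92 (adjusted p = 0.00286) and Dusp6 by 1.84 ± 0.45 (adjusted p = 0.00762), each in 4 of 4 arrays. Fgfr1 was lower (-2.20 ± 0.49, adjusted p = 0.00405, 4 of 4 arrays) but at 0.22 with the sample channel alone. Without ProCatxJOCK replicate 1 Fgfr1 was at -1.26, Tff3 at -2.79 and Sdhb, below, at 1.39. Ribosomal protein genes were higher (1.66, adjusted p = 1.18e-12, 17 of 30 over all genes and 26 adjusted over the list alone, adjusted p = 0.666 with an estimated correlation) but at -0.03 with the sample channel alone, Rpl14 by 2.44 ± 0.32 (adjusted p = 0.000198, 4 of 4 arrays) and Rps3 by 2.79 ± 0.53 (adjusted p = 0.00202, 4 of 4 arrays). Mitochondrial genes (0.54, adjusted p = 0.0193, 6 of 28 and 8, with 1 lower, adjusted p = 0.708) were higher but at -0.50 with the sample channel alone, the succinate dehydrogenase gene Sdhb by 2.25 ± 0.52 (adjusted p = 0.00588, 4 of 4 arrays). Endoplasmic reticulum genes (0.53, adjusted p = 0.0188, 4 of 22 higher and 1 lower on either count, adjusted p = 0.666) were higher but at -0.32 with it. Hypoxia and glycolysis genes were higher (0.46, adjusted p = 0.0272, 5 of 17 and 6, with 1 lower, adjusted p = 0.666), with the test pointing down at a median of 0.08 with the sample channel alone. The glycolysis gene Gapdh was higher by 1.86 ± 0.50 (adjusted p = 0.0144, 4 of 4 arrays), a call lost without ProCatxJOCK replicate 1 or 2 (up to 0.0677).

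Of 9726 genes 821 were higher and 1097 lower, with no array of the higher group above background for 17 and 53. The mitochondrial and endoplasmic reticulum calls were lost without ProCatxJOCK replicate 2 (0.28, adjusted p = 0.125, and adjusted p = 0.0528), and the hypoxia call without ProCatxJOCK replicate 2 or 3 or UbiCatxJOCK replicate 2 (up to 0.0572). Hypoxia genes were at 0.70 without ProCatxJOCK replicate 1 and 0.76 without UbiCatxJOCK replicate 4. The other 24 lists did not pass (smallest adjusted p = 0.0519), nor did 6 of the 12 fixed genes measured, from -0.81 to 3.03. The count was 1161 without ProCatxJOCK replicate 2, 1188 and 1205 without UbiCatxJOCK replicates 1 and 2, 1628 with slide as a random block and 1036 with only the groups compared. The split was 408 higher and 921 lower with no background correction, 1463 and 766 with the sample channel alone and 1084 and 220 with the scanner log ratio. The median of all genes moved by 0.20 and 0.52 under the last pair.

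Between the stromata of the crosses, Tshb was higher in UbiCatxJOCK by 6.56 ± 1.39 (adjusted p = 0.00153, at least 6.24-fold), Plppr1 by 5.24 ± 0.91 (adjusted p = 0.000338, at least 1.81-fold) and the seminal vesicle genes Svs6 by 6.43 ± 1.68 (adjusted p = 0.00684, at least 4.92-fold) and Svs4 by 5.23 ± 1.52 (adjusted p = 0.013, at least 3.54-fold), each in 4 of 4 arrays. Lower were Cygb (-3.99 ± 0.63, adjusted p = 0.000177, 4 of 4 arrays), Lbp, for a lipopolysaccharide-binding protein (-3.63 ± 0.92, adjusted p = 0.00577, 4 of 4 arrays), the Wnt receptor gene Fzd10 (-3.59 ± 0.73, adjusted p = 0.00117, 3 of 3 arrays) and Dusp6 (-1.36 ± 0.35, adjusted p = 0.00685, 4 of 4 arrays). Ribosomal protein genes were higher (0.97, adjusted p = 1.24e-06, 13 of 30 over all genes and 14 adjusted over the list alone, adjusted p = 0.653 with an estimated correlation), Rpl32 by 1.82 ± 0.33 (adjusted p = 0.000558, 4 of 4 arrays), though with the sample channel alone the list's test pointed down at a median of 0.24. Mitochondrial genes were higher (0.83, adjusted p = 3.26e-05, 10 of 28 and 13, adjusted p = 0.653) but at -0.35 with the sample channel alone. Cox6c was higher by 1.20 ± 0.19 (adjusted p = 0.000177, 4 of 4 arrays) but at -0.90 with it. Endoplasmic reticulum genes were higher (0.81, adjusted p = 0.000973, 5 of 22 over all genes and 4 adjusted over the list alone, adjusted p = 0.653), with the test pointing down at a median of 0.01 with the sample channel alone. The smooth muscle list was higher (0.95, adjusted p = 0.0357, 5 of 18 and 6, adjusted p = 0.781), Csrp1 by 2.26 ± 0.61 (adjusted p = 0.00832, 4 of 4 arrays), a call lost without ProCatxJOCK replicate 5 (adjusted p = 0.0519).

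Of 10130 genes 1179 were higher and 1886 lower in these 4 arrays against 3, and 567 of those lower were above background on no ProCatxJOCK array. The smooth muscle list lost its call without ProCatxJOCK replicate 5 or 7 or UbiCatxJOCK replicate 1 or 2 (adjusted p up to 0.134). The other 25 lists did not pass (smallest adjusted p = 0.0661), nor did 8 of the 13 fixed genes measured, from -0.94 to 5.13. A random slide block gave 2553 genes and only the groups compared 1810. The split was 1164 higher and 447 lower with the sample channel alone, 1825 and 566 with the scanner log ratio and 1298 and 1311 with the series matrix. The median of all genes moved by 0.27, 0.57 and 0.19 under these, by 0.17 with normexp and by 0.16 with no background correction.

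**Figure D4:**
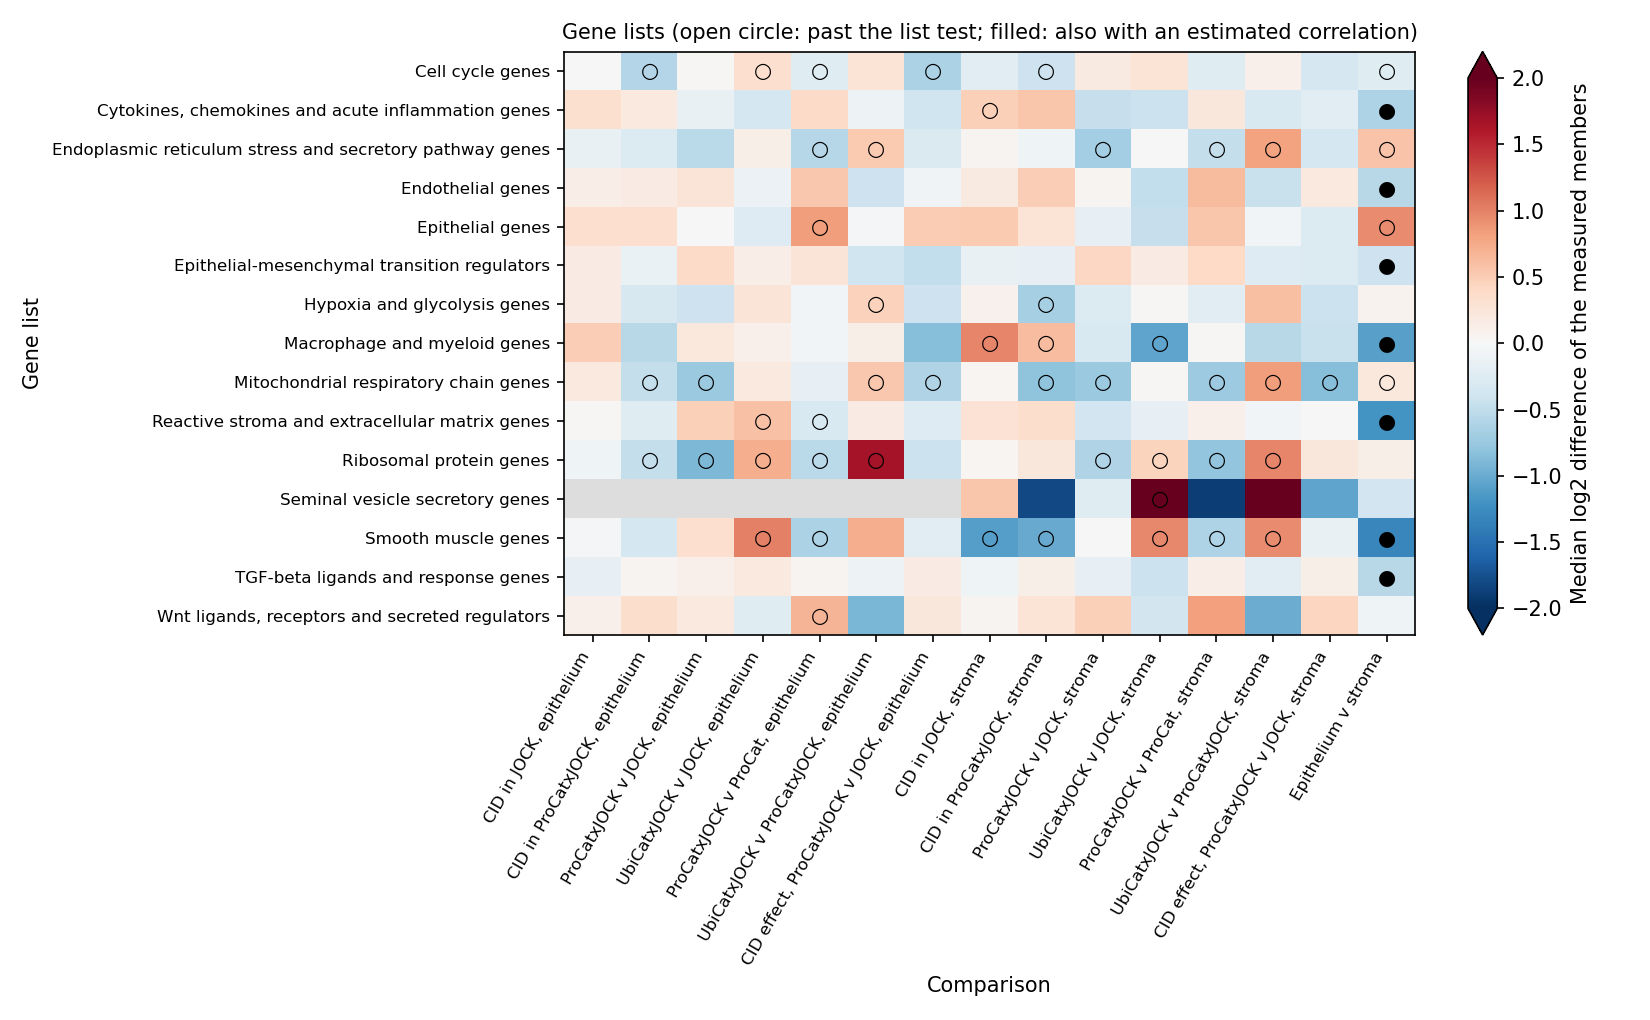
Median log2 difference of the measured members (colour) of each gene list that passed in at least 1 comparison (vertical axis), by comparison (horizontal axis), with colours ending at -2 and 2 and grey where a list was not tested. Open circles mark lists past the preset-correlation test and filled ones the 7 that held with an estimated correlation, all in epithelium against stroma; with the sample channel alone ribosomal protein genes in UbiCatxJOCK against ProCatxJOCK epithelium went from 1.66 to -0.03.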

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

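The tests of low signal, normalization, missing CID response, smooth muscle share and carry-over were chosen after the result was seen.

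Lone arrays lay far from the rest of their group in 5 of 82 groups tested, where chance gives about 1 in 20. ProCat stroma replicate 7 had a log2 ratio of 1.33 for Lrp5 (others -0.35 to 0.23) and 1.70 for Acta2 (others -0.43 to 0.42). UbiCatxJOCK stroma replicate 1 had 2.69 for Msmb (others 5.29 to 5.53), JOCK stroma with CID replicate 5 had -2.62 for Tgfb1 (others -1.57 to -1.16) and replicate 3 had -0.90 for Vim (others 0.44 to 0.52). The CID effect differed between ProCatxJOCK and JOCK for 55 genes in stroma, for mitochondrial genes in stroma (-0.85) and epithelium (-0.60) and for cell cycle genes in epithelium (-0.63), by tests of the difference itself. No list held with an estimated correlation (adjusted p = 0.971, 0.746 and 0.746), and both epithelial lists lost their call without single arrays.

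Single arrays were also split into other groups of the same sizes, which leaves chance differences between slides open. The real split gave most genes for epithelium against stroma (1 of 100 splits with as many, 2150 against at most 26). So it did for UbiCatxJOCK against JOCK (1 of 100 in epithelium, 367 against 3, and 1 of 100 in stroma, 480 against 61) and against ProCatxJOCK (1 of 35, 1918 against 576, and 1 of 35, 3065 against 829). In stroma it did for ProCatxJOCK against JOCK (1 of 84, 2604 against 93) and against ProCat (1 of 100, 3108 against 93). In epithelium 2 of 84 splits gave as many genes as ProCatxJOCK against JOCK (1375, highest other 1396, JOCK replicate 4 replacing ProCatxJOCK replicate 3). Against ProCat 2 of 100 did (1605, highest other 2226, the dim ProCat replicate 3 replacing it). The CID comparisons in ProCatxJOCK have 10 splits, too few for a share under 0.05: 3 gave as many in epithelium (123, highest other 181) and 1 in stroma (601, highest other 463).

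Macrophage genes were higher and smooth muscle genes lower with CID in the stroma of JOCK and ProCatxJOCK, as lists at the preset correlation. With an estimated one neither held (adjusted p = 0.138 and 0.58 in JOCK, 0.505 and 0.636 in ProCatxJOCK), and 0 of 17 macrophage genes passed in JOCK. In JOCK a lower share of smooth muscle in the captured stroma was argued against: macrophage genes exceeded endothelial, lymphocyte, adipocyte and neural genes by 0.91 (SE 0.22). A difference between slides was argued against: both signs held within 2 of 2. In ProCatxJOCK the excess was 0.64 (SE 0.47 over genes), so a lower share stays open there too. Slides were balanced for CID there, so a slide block had to return the same medians (0.61 and -1.01) and decides nothing. Both signs held within 1 of 2 slides, so a difference between slides stays open. A rise of macrophages with CID stays a hypothesis in JOCK, found and tested on the same data.

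ProCatxJOCK arrays lay apart from those of JOCK and ProCat. The normalization of the signals was not decided: as few as 45.5 percent of the changed genes kept their sign with the sample channel alone, which also drops the reference, and 89.9 to 99.6 percent under the 4 settings that keep it. Low signal of the ProCatxJOCK arrays was not decided: the percent changed among genes above background on every array was 0.933 times that among all genes in the comparison with JOCK epithelium, and higher than it in the other 3. Slides and scan days of their own could not be told apart from the model, as the differences from JOCK with and without CID correlated at up to 0.57. The alleles and the age of the mice stay open and untested.

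UbiCatxJOCK arrays lay against the direction of the CID effect. Stroma carried over into the captured epithelium could not be excluded. Smooth muscle genes exceeded macrophage genes by 1.11 (SE 0.35) there, but by 1.80 (SE 0.29) in stroma. The CID score of an array is the mean log2 ratio of genes that rose with CID in ProCatxJOCK minus that of genes that fell. Arrays labelled CID without a CID response could not be excluded: 6 of 8 scored at or below the highest untreated JOCK array. The 4 in epithelium (0.38 to 0.98) overlapped ProCat without JOCK (0.14 to 0.75), so the score cannot decide. The 2 in stroma tell nothing, as the score did not separate treated from untreated JOCK there (1.73 against 1.49, exact permutation p = 0.286). Dusp6 of all 4 epithelial arrays (0.03 to 0.91) was above both untreated JOCK arrays (-1.26 and -0.19), as the labels have it, and that of 1 of 4 stromal arrays was. A lower response caused by the UbiCat allele was not tested.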

How the results depend on the processing

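Normexp correction, the set without arrays under 5000 detected spots and the covariate were tests chosen after the result was seen.

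Aquantile normalization keeps log ratios, so it tests nothing. Testing every probe moved no count or gene past its threshold, but up to 57 genes per comparison had probes passing both ways. Of the 137 gene results named, 57 lost their call and 4 reversed with the sample channel alone, 33 lost it with a replicate block, 29 with only the groups compared, 27 with normexp, 25 with the series matrix, 23 with no background correction, 20 with the covariate (1 reversed), 11 without the dim arrays, 10 with no filter, 8 with array weights and 4 with the scanner log ratio. Trend and robust eBayes or a random slide block ended 1 call each, and a fixed one none of 42. Of the 57 list calls, 13 were lost and 19 reversed with the sample channel alone, 26 were lost with normexp, 26 with no background correction, 18 with the series matrix (1 reversed), 17 with the scanner log ratio, 15 without the dim arrays, 12 with the covariate, 8 with a replicate block, 7 with every probe tested, 6 with array weights, 4 with only the groups compared, 2 with no filter and 1 with trend and robust eBayes. With probes above background on every array 23 of the 48 list calls and 1 of the 24 genes that could be tested were lost. Over the 2080 gene results that the naming rule gave, 912 of them changed, 453 lost their call without at least 1 array, 410 with normexp (36 turned sign), 406 with the covariate (6), 403 with the sample channel alone (289), 389 with no background correction (23), 355 with a replicate block, 346 with the series matrix (41), 304 with only the groups compared, 270 with the scanner log ratio (6), 219 with array weights, 141 without the dim arrays, 121 with no filter (11), 82 with a random slide block, 22 with trend and robust eBayes and 16 with every probe (14). The cause was not tested for any value below.

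These counts moved over 1.5 times (epithelium then stroma where both did). The CID difference is that between ProCatxJOCK and JOCK. Array weights gave CID in JOCK 53 and 56, CID in ProCatxJOCK 17 and 106, the CID difference 17 in stroma, ProCatxJOCK against JOCK 820 and 1554, ProCatxJOCK against ProCat 591 in epithelium and UbiCatxJOCK against JOCK 3330 and 1732. With probes above background on every array CID in JOCK fell to 0 in epithelium, CID in ProCatxJOCK to 6 and 177, the CID difference to 10 in stroma, epithelium against stroma to 155, ProCatxJOCK against JOCK to 139 and 593, ProCatxJOCK against ProCat to 230 and 697, UbiCatxJOCK against JOCK to 82 and 102 and UbiCatxJOCK against ProCatxJOCK to 346 and 674. Those probes covered 934 of 9746 genes and 1219 of 10147. Trend and robust eBayes gave CID in JOCK 6 in epithelium and the CID difference 32 in stroma.

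With no background correction CID in JOCK was 21 and 50, CID in ProCatxJOCK 17 and 127, the CID difference 4 in stroma, ProCatxJOCK against ProCat 849 and 1835 and UbiCatxJOCK against JOCK 958 and 1268. Normexp gave CID in JOCK 20 and 46, CID in ProCatxJOCK 17 and 107, the CID difference 5 in stroma, ProCatxJOCK against ProCat 755 and 1588, UbiCatxJOCK against JOCK 906 and 1040 and UbiCatxJOCK against ProCatxJOCK 1051 in epithelium. The sample channel alone gave CID in JOCK 1 and 6, CID in ProCatxJOCK 344 and 918, the CID difference 36 in stroma, ProCatxJOCK against JOCK 1324 in stroma, ProCatxJOCK against ProCat 2424 and 1771, UbiCatxJOCK against JOCK 1022 and 1983 and UbiCatxJOCK against ProCatxJOCK 1611 in stroma. The scanner log ratio gave, in epithelium, CID in JOCK 14, CID in ProCatxJOCK 77, ProCatxJOCK against ProCat 833 and UbiCatxJOCK against JOCK 129. The series matrix gave CID in JOCK 9 and 15, CID in ProCatxJOCK 18 and 56, the CID difference 2 in stroma, ProCatxJOCK against JOCK 2287 in epithelium, ProCatxJOCK against ProCat 1910 in stroma and UbiCatxJOCK against JOCK 1205 and 1590. No filter gave CID in ProCatxJOCK 73 and 332 and the CID difference 21 in stroma.

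The covariate gave CID in JOCK 27 in epithelium, CID in ProCatxJOCK 254 and 376, ProCatxJOCK against JOCK 468 and 290, ProCatxJOCK against ProCat 867 in stroma, UbiCatxJOCK against JOCK 683 in epithelium and UbiCatxJOCK against ProCatxJOCK 1136 and 397. With only the groups compared CID in JOCK was 164 and 13, CID in ProCatxJOCK 1 and 0, the CID difference 10 in stroma, ProCatxJOCK against ProCat 486 and UbiCatxJOCK against JOCK 1460 in epithelium and UbiCatxJOCK against ProCatxJOCK 1036 and 1810. A fixed slide block gave CID in JOCK 13 and 41, CID in ProCatxJOCK 198 in epithelium and the CID difference 4 in epithelium, and a random one UbiCatxJOCK against JOCK 164 in stroma. Without the dim arrays CID in JOCK was 7 in epithelium, CID in ProCatxJOCK 199 and 216, the CID difference 14 in epithelium, ProCatxJOCK against ProCat 2438 in epithelium and UbiCatxJOCK against JOCK 722 and 727.

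By the labels replicate numbers do not pair samples. With replicate number as a block CID in JOCK was 0 and 5, CID in ProCatxJOCK 46 and 93, the CID difference 0 and 19, ProCatxJOCK against JOCK 224 and 2198, ProCatxJOCK against ProCat 685 and 2621, UbiCatxJOCK against JOCK 4 and 292, UbiCatxJOCK against ProCatxJOCK 1625 and 2047 and epithelium against stroma 2177. Deviations of same-numbered arrays of epithelium and stroma correlated at a median of 0.24 (17 of 21 pairs above 0.1), and at 0.22 (21 of 26) by the animals of the deposited names, where the block gave 2634, let Dusp6 pass and changed no other call named.

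Leaving out each array in turn gave CID in JOCK 1 to 9 and 11 to 56, CID in ProCatxJOCK 62 to 230 and 206 to 837, the CID difference 0 to 6 and 6 to 163, ProCatxJOCK against JOCK 613 to 2121 in epithelium, ProCatxJOCK against ProCat 945 to 2213 in epithelium, UbiCatxJOCK against JOCK 88 to 301 and 227 to 502 and UbiCatxJOCK against ProCatxJOCK 1161 to 2226 in epithelium. Of 1981 such fits of named genes 60 ended a call and 10 made one, but genes were named where possible among calls that no array ended. Of 988 such fits of lists 76 ended a call.

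Most reversals came with the sample channel alone. There Cox6c was at -0.90 in UbiCatxJOCK against ProCatxJOCK stroma, and Fgfr1 at -0.15 in ProCatxJOCK against JOCK, -0.22 in ProCatxJOCK against ProCat and 0.22 in UbiCatxJOCK against ProCatxJOCK epithelium. Cell cycle genes were at 0.18 in ProCatxJOCK against ProCat and -0.12 in UbiCatxJOCK against JOCK epithelium, Wnt ligands at -0.11 in ProCatxJOCK against ProCat epithelium and hypoxia genes at 0.08 in UbiCatxJOCK against ProCatxJOCK epithelium. Endoplasmic reticulum genes were at 0.40 and 0.10 in ProCatxJOCK against ProCat and -0.32 and 0.01 in UbiCatxJOCK against ProCatxJOCK. Mitochondrial genes were at 0.25 in ProCatxJOCK against JOCK epithelium, 0.11 in ProCatxJOCK against ProCat stroma and -0.50 and -0.35 in UbiCatxJOCK against ProCatxJOCK. Ribosomal protein genes were at -0.56 in ProCatxJOCK against JOCK epithelium, 0.69 and -0.31 in ProCatxJOCK against ProCat, -0.14 and -0.66 in UbiCatxJOCK against JOCK and -0.03 and 0.24 in UbiCatxJOCK against ProCatxJOCK. For lists whose median kept its sign, the test pointed the other way. Matrix genes were at 0.18 in ProCatxJOCK against ProCat epithelium with the series matrix, and Ctnnb1 at 0.13 in ProCatxJOCK against JOCK stroma with the covariate.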

Other observations

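All tests of single values in this part were chosen after the result was seen.

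In JOCK epithelium, Dusp6 log2 ratios averaged 2.02 (SD 0.73, n = 6) with CID against -0.72 without it (n = 2). Every treated array was above both untreated ones (exact permutation p = 0.0357 over 28 splits, too low as fewer exist within slides). In stroma the means were 1.24 (SD 0.30) and -0.32, with the same n and p. ProCatxJOCK arrays with CID ran from 1.47 to 3.31 in epithelium and 0.39 to 1.17 in stroma, and those without it from -0.72 to 0.11 and -0.40 to 0.10. UbiCatxJOCK arrays, all labelled CID, ran from 0.03 to 0.91 and -1.33 to 0.25, and ProCat arrays from -2.06 to -0.91 and -1.62 to -0.19.

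Over the 9628 genes in epithelium and 9957 in stroma with values in all 4 groups of JOCK and ProCatxJOCK, their CID effects correlated at 0.34 and 0.16. Of the genes changed in ProCatxJOCK, 86 of 123 and 343 of 598 had the same sign in JOCK, and of those changed in JOCK, 3 of 3 and 3 of 24 had it in ProCatxJOCK. Without CID, ProCatxJOCK differed from JOCK in 475 and 667 genes. Of the 1358 and 2553 of these genes that differed with CID, 1236 and 2122 had the same sign without it.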
